A study of Homo sapiens with 10 samples.

How the data were processed

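Gene expression was measured in subcutaneous tumours of A375, an established human melanoma cell line, grown in immunodeficient nude mice. Per the labels' protocols, the mice drank doxycycline or its vehicle from a tumour volume of 100 mm3 on, doxycycline switching on Omomyc in the tumour cells, and tumours were taken 7 days later. Omomyc is a mutated fragment of MYC that acts as a dominant negative. The labels name 5 vehicle and 5 doxycycline tumours as biological replicas, 1 array each. The protocols also speak of tumours of a second line, SkMel147, which were not analysed here. The series holds no doxycycline-treated tumours lacking Omomyc, so an effect of Omomyc and an effect of doxycycline itself are not separated by the design. No batch or date is given in the labels.

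Per the labels' protocols, total RNA was extracted with TRIzol from frozen tissue and labelled with biotin, and per the series design it was hybridised to Affymetrix arrays. The values deposited by the authors are log2 expression values, made with RMA per the submitters' processing notes. The RMA version, the array model and the genome build are not given in the sources used here, so no coordinates are printed. The table holds 18569 probe sets for 10 arrays. Of these, 17511 carried 1 gene symbol in the platform annotation, 0 carried several and 1058 had no listed gene. All 17511 Entrez identifiers matched the gene table, and 0 symbols were changed by it. For the 17 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 17492 genes. RNA of the mouse host is part of the tissue and can hybridise to probes for human genes. The number of arrays limits the precision.

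Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the single term, all 10 arrays), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Changes are doxycycline minus vehicle on the log2 scale. Gene lists were tested with camera at its preset correlation of 0.01, with adjustment over the 37 lists that had at least 5 measured members. Of the 38 lists written, the mitochondrially encoded genes had no measured member. Camera with an estimated correlation and fry were run as alternatives. The mean log2 value over each list was also compared between the groups by an exact two-sided permutation test over all 252 splits of the arrays, whose smallest possible p is 0.00794. The lists share members, 38 of their 879 distinct genes being in more than 1 list.

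The grouping, the tests, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule takes the 10 largest rises and the 10 largest falls among genes past the threshold whose doxycycline arrays all lie on one side of all vehicle arrays. It adds every measured member of the MYC network list. It also adds up to 4 members with the smallest p of each list that passed the threshold or held 3 or more changed genes, and 1 member of every other list. XIST, Y-linked genes and symbols starting with LOC were left out of the largest changes. The rule gave 130 genes. Genes outside it are said to have been chosen after their values were seen.

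The alternatives were the replicate number as a block, trended and robust moderation, array weights, median centring, a second quantile normalization, removal of the dimmest 30% of genes, the mean over probe sets, a stroma score as a covariate, Welch's test per gene, a minimum change of 1.5-fold, all probe sets, and each array left out in turn. The stroma score was the mean per array over the endothelial, macrophage and monocyte, and fibroblast and pericyte markers, each gene centred on its mean. Leaving out doxycycline arrays 4 and 5 together, and a further 6 gene lists, were chosen after seeing the data. The procedure was tested on simulated data for the comparison of doxycycline with vehicle, over 17492 genes. It recovered 14.9% of genes changed by 0.5, 65.7% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale, with 3 false calls among 122, and called 0 of 30 unchanged lists. That simulation drew genes independently, so it does not test lists whose genes vary together. It changed 67, 67 and 66 genes by 0.5, 1 and 2 and gave both groups equal variances. Its rates may therefore differ from those in data with 1921 called genes.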

Results

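Expression was compared between 5 vehicle-treated and 5 doxycycline-treated A375 melanoma xenografts, each on 1 array. The series title names the effect of Omomyc on melanoma growth in vivo as its subject, and the comparison asks which transcripts differ after 7 days of treatment. Correlations between arrays were 0.979 to 0.987 within the vehicle group, 0.965 to 0.985 within the doxycycline group and 0.954 to 0.974 between groups. The first principal component held 33.8% of the variance and separated the groups. Doxycycline arrays 4 and 5 had the lowest mean correlations with their own group, 0.973 and 0.9669.

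Genes of hypoxia, cholesterol synthesis, mitosis and nucleotide synthesis were lower in the doxycycline-treated tumours, and p53 target, lysosomal and interferon-response genes were higher. With an estimated correlation the cholesterol and lysosome lists passed (both adjusted p = 0.0123), but hypoxia, mitosis, nucleotide synthesis, p53 targets and the interferon response did not (adjusted p = 0.157, 0.157, 0.0919, 0.115 and 0.181 with an estimated correlation). Known MYC target genes were lower by a median of 0.20 on the log2 scale, and 15 of 48 fell (adjusted p = 0.157 with an estimated correlation). CA12, a carbonic anhydrase induced by hypoxia, fell by 3.62 (95% CI -4.41 to -2.83, n = 5 per group). PAGE1, a cancer-testis antigen, rose by 3.33 (95% CI 2.68 to 3.98). Over all 17492 genes, limma called 880 higher and 1041 lower, 618 and 805 of them by at least 1.5-fold.

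In 2065 genes, 11.8% of all, the 5 doxycycline arrays lay entirely above or entirely below the 5 vehicle arrays, against 0.794% by chance. The median change of all genes was 0.02. With a test per gene that neither moderated the variances nor took them as equal in both groups, 578 genes were called higher in place of 880. That test called 706 genes lower in place of 1041. The design does not separate Omomyc from doxycycline itself.

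**Figure D1:**
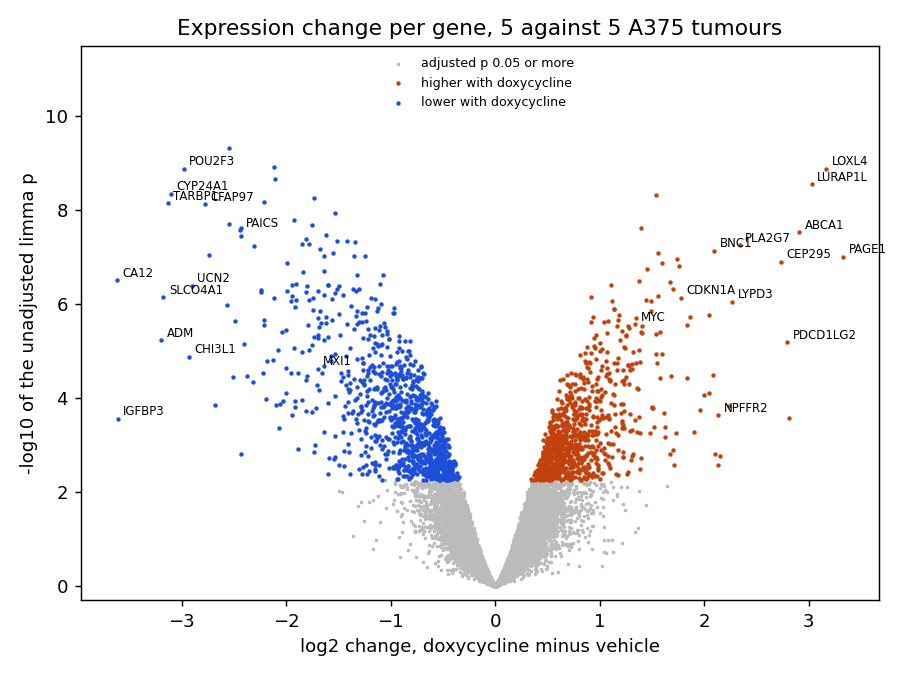
Each point is 1 gene, with its log2 change (doxycycline minus vehicle) on the horizontal axis and -log10 of its unadjusted limma p on the vertical axis. The 880 higher genes are orange, the 1041 lower genes blue and the others grey, and PAGE1 and CA12 lie farthest out on either side among the labelled genes.

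Among changed genes whose groups did not overlap, the largest rises after PAGE1 were those of LOXL4, a lysyl oxidase family member (3.17, adjusted p = 5.72e-06), LURAP1L (3.03), the cholesterol exporter ABCA1 (2.91) and the immune checkpoint ligand PDCD1LG2 (2.79, adjusted p = 0.000615). CEP295, PLA2G7, LYPD3, NPFFR2 and BNC1 rose by 2.74, 2.34, 2.27, 2.13 and 2.10. The largest falls of such genes after CA12 were those of the growth factor binding protein IGFBP3, which fell by 3.61 with an SD of 1.91 among the doxycycline arrays (adjusted p = 0.00677), and of the peptide hormone gene ADM, which fell by 3.19. The transporter gene SLCO4A1 fell by 3.18, TARBP1 fell by 3.13 and CYP24A1, which encodes a vitamin D-degrading enzyme, fell by 3.10. POU2F3, CHI3L1, UCN2 and CFAP97 changed by -2.98, -2.93, -2.90 and -2.78. With that unmoderated test of unequal variances, IGFBP3 had an adjusted p of 0.0944 and NPFFR2 an adjusted p of 0.0663.

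In the MYC network, the MYC probe set rose by 1.34 (95% CI 0.983 to 1.69, adjusted p = 0.000348), from 6.35 ± 0.21 to 7.69 ± 0.30 (SD, n = 5 each), and all 5 doxycycline arrays lay above all vehicle arrays. Omomyc derives from MYC, and the table holds no value per probe, so transcripts of Omomyc and of the cells' own MYC are not separated in this value. MXI1, which encodes a MAX partner that antagonises MYC, fell by 1.70 (adjusted p = 0.00148), and MGA fell by 0.92 (adjusted p = 0.0268). The call of MGA was lost without vehicle array 1, 2 or 4 (adjusted p = 0.0673, 0.0518 and 0.0638), with the stroma score as a covariate (adjusted p = 0.0869) and with the unmoderated test (adjusted p = 0.129). MAX, the obligate partner of MYC, differed by 0.44 (adjusted p = 0.0512). MXD1 differed by -0.41 (adjusted p = 0.0569) and MLXIP by -0.62 (adjusted p = 0.0675). MYCN, MNT, MXD3, MLXIPL, MLX and MYCL differed by 0.17, 0.16, 0.05, 0.02, -0.05 and -0.07 and did not pass. Of the 12 measured members 1 was higher and 2 were lower, or 2 and 4 adjusted over the list alone, and the list did not pass with camera (adjusted p = 0.664), while its mean was lower by the exact permutation test (adjusted p = 0.0326). Without vehicle array 1, 2 or 4, 1 member was lower, and without doxycycline array 5, 2 were higher.

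MYC targets fell as a list (camera, adjusted p = 1.07e-05), but not with an estimated correlation (adjusted p = 0.157 with an estimated correlation). Of 48 measured members, 15 fell and 0 rose, and adjusted over the list alone 18 fell and 2 rose. TMEM97 fell by 2.11, the mitochondrial chaperone HSPD1 fell by 1.62, IMP4, a ribosomal RNA processing factor, fell by 1.24, and the nucleoside transporter SLC29A2 fell by 1.27. The mean over the list was 8.05 ± 0.06 in vehicle and 7.70 ± 0.07 in doxycycline tumours (SD, n = 5 each, exact permutation test, adjusted p = 0.0226). Of 18 measured genes known to be repressed by MYC, 4 rose and 2 fell, or 4 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.685). The cell cycle inhibitor CDKN1A rose by 1.78 and the integrin ITGA6 by 0.74, while TXNIP fell by 2.22 and NDRG1 fell by 1.71.

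Lists for the making of ribosomes fell. In ribosome biogenesis, 11 of 35 members fell and 1 rose, with 15 and 3 adjusted over the list alone (camera, adjusted p = 0.000149; adjusted p = 0.239 with an estimated correlation). The nucleolar methyltransferase FBL fell by 1.74, NAT10 fell by 1.21, NOB1 fell by 0.71 and nucleolin, NCL, fell by 0.70. Without vehicle array 1, 3, 4 or 5, 7 members fell in place of 11. Of 23 ribosomal protein genes 1 fell, RPL10A, by 0.39 (adjusted p = 0.0464), and 0 did adjusted over the list alone. RPL19, RPL27 and RPL14 differed by -0.29, -0.32 and -0.21 and did not pass. This list passed with camera (adjusted p = 0.0181) but not with an estimated correlation (adjusted p = 0.546 with an estimated correlation) or in the exact permutation test (adjusted p = 0.0534). It also missed the threshold without vehicle array 2 (adjusted p = 0.0518), without doxycycline array 5 (adjusted p = 0.0511) and without doxycycline arrays 4 and 5 (adjusted p = 0.158), as well as after a second quantile normalization (adjusted p = 0.0686) and with the stroma score as a covariate (adjusted p = 0.0505). Of 22 tRNA synthetases and translation factors 3 fell, EIF4EBP1 by 0.88, IARS1 by 0.86 and EPRS1 by 0.44, and the list did not pass with camera (adjusted p = 0.121), but did in the exact permutation test (adjusted p = 0.0326). AARS1 differed by 0.38 (adjusted p = 0.066). Adjusted over the list alone, 3 fell and 1 rose.

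Metabolic lists fell. In nucleotide synthesis 9 of 21 members fell, 14 adjusted over the list alone, and 0 rose (camera, adjusted p = 1.10e-07; adjusted p = 0.0919 with an estimated correlation). PAICS, a purine synthesis enzyme, fell by 2.44, PPAT, which catalyses the committed step of that pathway, fell by 1.01, CTPS1 fell by 0.72 and PRPS2 fell by 0.57. In serine, one-carbon and polyamine synthesis 7 of 14 fell, 8 adjusted over the list alone (adjusted p = 6.17e-07; adjusted p = 0.0623 with an estimated correlation). The mitochondrial folate enzyme MTHFD2 fell by 1.85, the amino acid transporter SLC7A5 fell by 1.69, SMS fell by 1.11 and MTHFD1 fell by 0.59. In glycolysis 10 of 18 fell, 15 adjusted over the list alone, where 1 rose (adjusted p = 6.86e-10; adjusted p = 0.13 with an estimated correlation). ALDOC fell by 1.47, PFKL fell by 1.15, LDHA fell by 1.09 and GPI fell by 1.03.

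In oxidative phosphorylation 6 of 23 members fell, 8 adjusted over the list alone (camera, adjusted p = 1.53e-05; adjusted p = 0.181 with an estimated correlation). ATP5PO fell by 0.53, UQCRC2 fell by 0.50, ATP5F1C fell by 0.49 and NDUFA9 fell by 0.46. The count was 3 without vehicle array 1, 2, 4 or 5 or doxycycline array 1, and 2 without doxycycline arrays 4 and 5. In cholesterol synthesis 14 of 20 members fell, 17 adjusted over the list alone, with a median of -0.78 (camera, adjusted p = 1.82e-14), and the call held with an estimated correlation (adjusted p = 0.0123). INSIG1, a sterol sensor, fell by 1.55, ACAT2 fell by 1.39, the squalene epoxidase SQLE fell by 1.19 and MSMO1 fell by 0.94.

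The hypoxia response had the largest median among the lists, -1.28, and 16 of its 22 members fell (camera, adjusted p = 1.27e-14; adjusted p = 0.157 with an estimated correlation). Adjusted over the list alone, 19 fell and 1 rose. Beside CA12, ADM and MXI1, the lipid droplet gene HILPDA fell by 2.00. The list mean was 8.32 ± 0.32 in vehicle and 6.96 ± 0.45 in doxycycline tumours (SD, n = 5 each, exact permutation test, adjusted p = 0.0226), and 6 of its members belong to other lists too.

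Mitosis genes fell, 26 of 38 with a median of -0.72, or 32 adjusted over the list alone, and 0 rose (camera, adjusted p = 9.05e-19; adjusted p = 0.157 with an estimated correlation). The condensin gene NCAPG fell by 1.03, the kinesin gene KIF2C fell by 1.03, CDK1, the kinase that drives entry into mitosis, fell by 0.99 and NEK2 fell by 0.92. The count was 16 without vehicle array 4 and 17 without doxycycline array 2. In DNA replication 5 of 35 fell, 8 adjusted over the list alone, and 1 rose (adjusted p = 0.000245; adjusted p = 0.541 with an estimated correlation). ORC1 fell by 0.75, CDC45 fell by 0.66 and RFC4 fell by 0.52, while the cyclin gene CCNE1 rose by 1.14. The list did not pass with fry (adjusted p = 0.136) or in the exact permutation test (adjusted p = 0.122). The count of lower members was 2 without vehicle array 1, 3, 4 or 5 or doxycycline array 2, 3 without doxycycline array 1 and 8 without vehicle array 2.

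Targets of p53 rose, 11 of 22 with a median of 0.64, while 0 fell (camera, adjusted p = 1.11e-06; adjusted p = 0.115 with an estimated correlation). Adjusted over the list alone, 13 rose and 1 fell. Beside CDKN1A, TP53INP1 rose by 1.54, ZMAT3 by 1.40 and MDM2, the ubiquitin ligase that degrades p53, by 1.14. Among 21 apoptosis regulators 3 rose and 1 fell, or 5 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.492). BCL2L1 rose by 0.82, BAX by 0.66 and XIAP by 0.59, and BNIP3 fell by 1.46. Immediate early genes rose, 5 of 19 (camera, adjusted p = 0.00164; adjusted p = 0.181 with an estimated correlation), with 7 higher and 2 lower adjusted over the list alone. IER5 rose by 0.85, ZFP36 by 0.73, KLF6 by 0.62 and IER2 by 0.55. The count was 3 without vehicle array 1, 3 or 4, without doxycycline array 4, or without doxycycline arrays 4 and 5.

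Lysosome and autophagy genes rose, 12 of 25, or 16 adjusted over the list alone, with a median of 0.41 (camera, adjusted p = 4.77e-10), and the call held with an estimated correlation (adjusted p = 0.0123). The cathepsin genes CTSF, CTSL and CTSA rose by 1.45, 1.19 and 0.81, and the autophagy gene WIPI1 by 0.95. Macrophages are rich in lysosomes, and the mean over macrophage and monocyte markers was also higher, 4.17 ± 0.14 against 3.95 ± 0.08 (SD, n = 5 each, exact permutation test, adjusted p = 0.0326), although that list did not pass with camera (adjusted p = 0.103). Both means lay below the median of every array, 5.43 to 5.53. Relative to vehicle, doxycycline array 4 was highest for both lists, at 0.644 for lysosome genes and 0.37 for macrophage markers. Array 5, at 0.361 for macrophage markers, was lowest of the doxycycline arrays for lysosome genes, at 0.42. The lysosome list kept its call with the stroma score as a covariate. That score averages macrophage with endothelial and fibroblast markers, so it does not adjust for macrophages alone. Whether macrophages account for the rise was not tested.

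Interferon-response genes rose, 11 of 37, or 13 adjusted over the list alone, with a median of 0.36 (camera, adjusted p = 2.53e-06; adjusted p = 0.181 with an estimated correlation). SAMD9L rose by 2.05, IFIT2 by 1.56, the transcription factor IRF1 by 1.38 and IFIT3 by 1.27. The mean over the list, relative to the vehicle mean, was 0.573, 0.657, 0.778, 0.252 and 0.0364 in doxycycline arrays 1 to 5, so that array 5 lay within the vehicle range of -0.0882 to 0.0446. Without doxycycline arrays 4 and 5, left out together after the data were seen, 18 members were higher. Of 20 antigen presentation genes 4 rose, B2M by 0.59, ERAP2 by 1.10, TAPBP by 0.61 and CIITA by 0.82, and 9 did adjusted over the list alone (camera, adjusted p = 6.45e-05; adjusted p = 0.157 with an estimated correlation). In the exact permutation test of the list means the adjusted p was 0.0534. The count was 7 without doxycycline array 5 and 7 without both arrays. Macrophage and monocyte markers were higher by 0.217 in mean over all doxycycline arrays, and relative to the vehicle mean they were at 0.128, 0.153, 0.0735, 0.37 and 0.361 in doxycycline arrays 1 to 5.

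**Figure D2:**
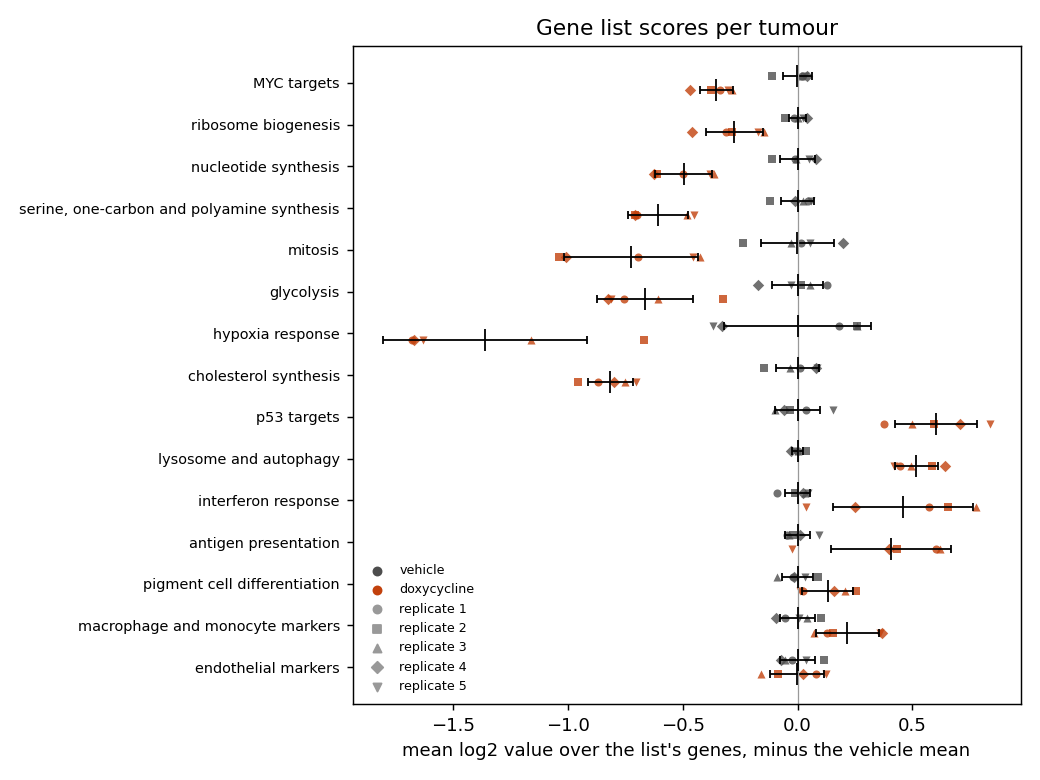
Each marker is 1 tumour, placed at the mean log2 value over a gene list minus the mean of the vehicle group, with black bars for the group mean ± SD (n = 5 each). The hypoxia, cholesterol and nucleotide lists separate the groups in every tumour, while doxycycline replicate 5 lies at 0.0364 for the interferon list.

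Doxycycline inhibits mitochondrial translation, and a list of genes that respond to it or to mitochondrial stress fell, with 6 of 14 lower and 1 higher, or 7 and 2 adjusted over the list alone (camera, adjusted p = 0.00155; adjusted p = 0.0623 with an estimated correlation). Its 4 members with the smallest p were HSPD1, MTHFD2, HSPE1, which fell by 1.06, and the cystine transporter SLC7A11, which fell by 0.99. Mitochondrial stress predicts a rise of its amino acid stress genes, so the fall of the list is no sign of such stress. Of its members 11 are shared with other lists, among them HSPD1 and HSPE1 with the MYC targets. The unfolded protein and amino acid stress response did not pass (adjusted p = 0.822). Of its 24 members 2 rose and 3 fell, or 4 and 6 adjusted over the list alone. DNAJB9 rose by 0.99 and SESN2 by 0.70, while DDIT4 fell by 2.51. Of 17 heat shock proteins 1 fell, the chaperonin gene CCT5, by 0.52, as adjusted over the list alone (camera, adjusted p of the list 0.121; exact permutation test, adjusted p = 0.0326).

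Melanoma state lists did not pass. Of 21 pigment cell differentiation genes 1 rose, CAPN3, by 1.73, and 3 did adjusted over the list alone (adjusted p of the list 0.63). The count was 3 without doxycycline array 5 and 2 without vehicle array 1 or 3 or doxycycline array 1. Of 22 genes of the undifferentiated state 1 rose, NGFR, by 1.01, and 1 fell, against 2 and 4 adjusted over the list alone (adjusted p of the list 0.787). Without doxycycline array 5, 2 rose and 3 fell, without vehicle array 5, 2 rose and 0 fell, and without vehicle array 2 or 3 or doxycycline array 1 or 4, 0 fell. Of 18 MAPK pathway output genes DUSP5 rose by 0.61, EPHA2 by 0.53 and LIF fell by 0.81, the same counts as adjusted over the list alone, and SPRY4 differed by 0.51 (adjusted p = 0.0826). That list had an adjusted p of 0.181, of 0.0295 without doxycycline array 5, of 0.0193 without doxycycline arrays 4 and 5 and of 0.0234 with the stroma score as a covariate. Of 24 cytokine and NF-kB target genes 1 rose, CSF1, by 0.95, and 1 fell, as adjusted over the list alone (adjusted p of the list 0.83).

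Among 23 collagen and matrix genes 3 rose and 5 fell, or 4 and 7 adjusted over the list alone, and the list did not pass (adjusted p = 0.121), except without doxycycline array 2 (adjusted p = 0.0405). COL6A2 fell by 2.00, COL6A1 fell by 1.16 and the laminin gene LAMA4 fell by 1.15, while the fibrillin gene FBN1 rose by 1.07. Of 21 macrophage and monocyte markers 2 rose, the same number adjusted over the list alone, and LYZ, lysozyme, rose by 1.28. That list passed with camera without doxycycline array 3 (adjusted p = 0.0478). Of 20 endothelial markers 1 rose and 1 fell, as adjusted over the list alone, and ECSCR fell by 2.12 (adjusted p of the list 0.913). Of 19 fibroblast and pericyte markers 1 rose, C1S, by 0.57, against 3 higher and 2 lower adjusted over the list alone (adjusted p of the list 0.913). Of 12 neutrophil and mast cell markers 1 rose, MPO, by 0.50, and of 13 keratinocyte and skin markers 1 fell, SBSN, by 1.11, both counts as adjusted over the list alone (adjusted p of the lists 0.624 and 0.913). The levels were low, C1S moving from 2.46 to 3.03 and MPO from 2.93 to 3.42. The 25th percentiles of the arrays were 3.40 to 3.58. No member passed, over all genes or adjusted over the list alone, among 15 lymphocyte, 11 adipocyte, 15 skeletal muscle and 8 erythroid markers (camera, adjusted p = 0.965, 0.492, 0.437 and 0.624). Their members with the smallest p were CD3D at -0.89, GPD1 at 0.65, NEB at 0.32 and EPB42 at 0.31.

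**Figure D3:**
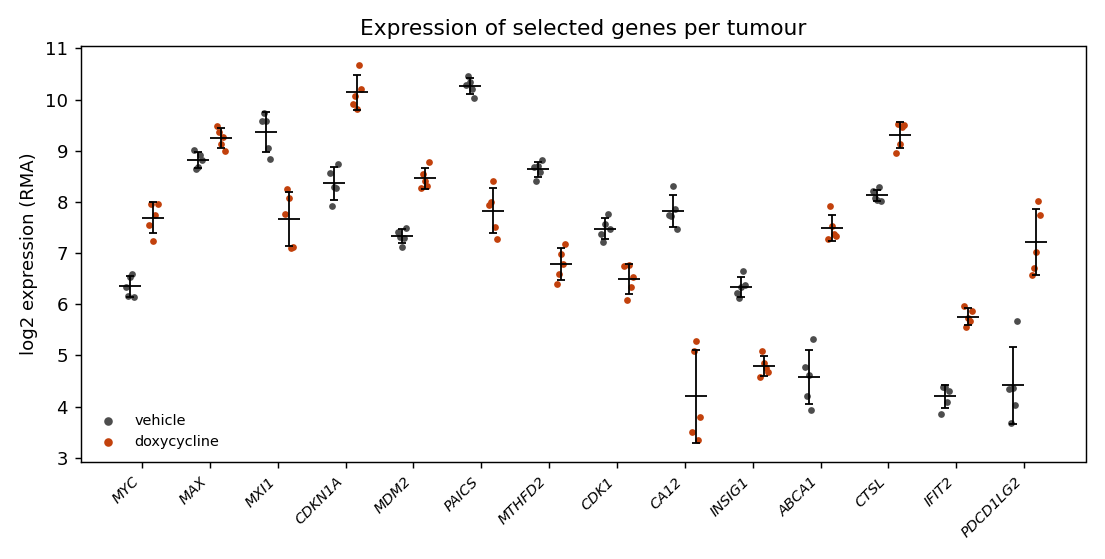
Log2 expression (RMA) of selected genes, with 1 point per tumour and black bars for the group mean ± SD (n = 5 each). MYC moves from 6.35 to 7.69 and CA12 from 7.82 to 4.20, while the MAX values of the groups overlap.

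Calls of 14 named genes were lost when 1 array was left out, with the adjusted p-values in parentheses. Beside MGA, RFC4 was lost without vehicle array 3 (0.0562) and ATP5F1C without vehicle array 2 or 3 (0.0523 and 0.0547). NDUFA9 was lost without vehicle array 1, 4 or 5 or doxycycline array 1 (0.0539 to 0.0577), CDC45 without vehicle array 1, 4 or 5 or doxycycline array 1 or 2 (0.0571 to 0.0672), and XIAP without vehicle array 1, 3 or 5 or doxycycline array 2 or 3 (0.0567 to 0.0647). EPRS1 was lost without vehicle array 1, 2, 3 or 4 or doxycycline array 2 or 4 (0.0567 to 0.0901), and MPO without vehicle array 1, 3 or 4 or doxycycline array 2, 4 or 5 (0.0503 to 0.0932). IER2 kept its call in 3 of the 10 fits with 1 array left out, without vehicle array 5 or doxycycline array 2 or 3, and LIF in 3, without vehicle array 5 or doxycycline array 1 or 3 (otherwise up to 0.0817 and 0.0902). SBSN kept it in 3, without vehicle array 1 or 5 or doxycycline array 5, EPHA2 in 2, without vehicle array 1 or doxycycline array 2, C1S in 2, without vehicle array 4 or doxycycline array 4, and RPL10A in 1, without doxycycline array 3 (otherwise up to 0.0761, 0.1, 0.0938 and 0.116). With the stroma score as a covariate 13 named genes were lost, MGA, RPL10A, EPRS1, ATP5F1C, NDUFA9, BCL2L1, LIF, EPHA2, TAPBP, MPO, C1S, SBSN and IER2 (0.0541 to 0.127). The unmoderated test lost 19, which beside IGFBP3, NPFFR2 and MGA were NDRG1, ATP5F1C, CDC45, BCL2L1, XIAP, CAPN3, DUSP5, LIF, EPHA2, TAPBP, CIITA, MPO, C1S, SBSN, ZFP36 and IER2 (up to 0.135).

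Some small counts of list members moved as well. Without vehicle array 1, 2, 3 or 4 or doxycycline array 2, 4 or 5, 0 MAPK output and 0 cytokine genes were lower, and without vehicle array 5, 2 cytokine genes were. Without vehicle array 2, 3, 4 or 5 or doxycycline array 1 or 4, 1 MAPK output gene was higher, and without doxycycline array 3 or 4, 2 cytokine genes were. In the doxycycline and mitochondrial stress list 0 genes were higher without vehicle array 1, 4 or 5 or doxycycline array 2, 4 or 5. Macrophage markers higher numbered 1 without vehicle array 1, 3 or 4, endothelial markers higher 2 without doxycycline array 5 and lower 2 without doxycycline array 2, and fibroblast markers lower 2 without doxycycline array 5 and 1 without doxycycline array 3. Apoptosis regulators lower numbered 2 without doxycycline array 2. Counts of 0 became 1 for heat shock proteins higher and interferon genes lower without vehicle array 2, and for lymphocyte markers lower without vehicle array 4. They also did for immediate early and pigment genes lower without doxycycline array 2, and for hypoxia genes, skeletal muscle markers and tRNA synthetases and translation factors higher without doxycycline array 4.

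For the MYC-repressed, cytokine, endothelial, lymphocyte and keratinocyte lists, none of which passed, the median, the mean and the camera direction did not share one sign. In all, 17 of the 37 lists passed with the preset correlation, 5 higher and 12 lower, and 2 with an estimated correlation, lysosome and autophagy and cholesterol synthesis. In the exact permutation test of list means 18 lists had an adjusted p under 0.05. With fry 20 lists passed, which left out DNA replication and added tRNA synthetases and translation factors (adjusted p = 0.0458), heat shock proteins (0.015), macrophage and monocyte markers (0.0219) and adipocyte markers (0.0458).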

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

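The tests below on the MYC probe set, on doxycycline array 5 and on the fall of the mitosis, hypoxia and cholesterol lists were chosen only after the results were seen. In 334 sets of 5 arrays, 1 array lay apart from the other 4 by more than Dixon's limit of 0.71 in 21 cases, where chance gives about 1 in 20, or 16.7. Doxycycline array 4 accounted for 5 of these, vehicle array 2 for 4, and doxycycline array 5 and vehicle array 3 for 3 each. In doxycycline array 4, CEP295 was at 7.92 against 9.19 to 9.22 in the others of its group, FBL at 7.06 against 7.98 to 8.11 and MGA at 4.99 against 6.04 to 6.39. In that array NAT10 was at 6.19 and CSF1 at 8.19. In doxycycline array 5, PLA2G7 was at 6.70, LYZ at 6.57 and the MAPK output list at -0.256 against 0.148 to 0.299. In vehicle array 2, the MYC target list was at -0.111 against 0.0165 to 0.0403, NAT10 at 7.91, ATP5PO at 9.57 and the skeletal muscle list at 0.119. In vehicle array 3, TAPBP was at 7.46, GPD1 at 2.04 and NEB at 4.13. AARS1 at 8.71 and CAPN3 at 3.20 stood out in vehicle array 5, and HSPE1 at 9.58 in vehicle array 1. In doxycycline array 1 the oxidative phosphorylation list was at -0.316 and SESN2 at 5.83, and in doxycycline array 2 COL6A1 was at 9.64.

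The MYC probe set was higher in 5 of 5 doxycycline arrays than in any vehicle array while MYC targets were lower. A candidate explanation is that the probe set reads the Omomyc transcript, but a rise of the cells' own MYC predicts the same 5 arrays, and the values cannot be told apart without probe-level data. An exchange of the labels of some arrays was argued against, since 0 arrays lay within the other group's range for the MYC target score. The same 0 for MYC restates the pattern itself. An exchange of all labels would also give 0.

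The interferon score of doxycycline array 5 lay at the vehicle level, differing by -0.529 from the mean of the other 4 doxycycline arrays. Lower induction in that tumour stays open. Its MYC probe set, at 7.956, was 0.333 above the mean of the other 4. It lay just within their range of 7.24 to 7.96, whose highest value was 7.957. The bound first written, the mean of the other 4, would have excluded lower induction. Whether that probe set measures induction is itself not known. Scores relative to vehicle went both ways, with p53 targets at 0.839, the highest of the doxycycline arrays, hypoxia at -1.63 and glycolysis at -0.814. The 127 genes of the next test lay higher than in the other 4. Dilution of tumour RNA alone was argued against, since 127 MYC target, nucleotide, mitosis and cholesterol genes had a median deviation of 0.19 (95% bootstrap interval over genes 0.113 to 0.259). That interval resamples genes of 1 array and does not measure the spread between tumours. These lists fell with treatment, so a weaker response in that tumour could mask dilution. Host marker genes deviated by 0.135, the 95.16th percentile of level-matched random lists, below the limit set and too near it to exclude more host RNA. An earlier form of that test, which set arrays 4 and 5 against the other 3, had passed the limit and was withdrawn because the data had defined the split; the bounds for exclusion in the host and induction tests were set after the values were seen.

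The fall of the mitosis, hypoxia and cholesterol lists could come from a smaller share of A375 RNA in treated tumours. The 8 expressed pigment lineage genes did not fall with them, at a median change of 0.248 (95% bootstrap interval over genes -0.0491 to 0.516), against -0.718 for mitosis. That interval does not measure the spread between tumours. A rise of these genes with treatment could mask a smaller share, so the test cannot exclude it. The list of genes that respond to doxycycline or mitochondrial stress had 6 of 14 members lower and 1 higher, but shares 11 members with other lists. Of 6 amino acid stress genes, which such stress predicts to rise, 0 rose and 1 fell, PSAT1 (-0.989, adjusted p = 0.00856). CHAC1, at 1.03, did not pass (adjusted p = 0.0568). The calls among these 6 genes give no sign of mitochondrial stress from doxycycline itself. They do not cover the 1 higher member of the 14, which is not among the 6. Such stress stays open, since the 6 genes had a median of -0.00631 with a bootstrap interval over genes of -0.693 to 0.574. The reading of that test was changed from a count of called genes, by which stress would have been excluded, to this interval after the value was seen. A biological effect of Omomyc and an effect of doxycycline are confounded by the design.

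Chance was argued against for the number of changed genes. Of 100 splits drawn from the 126 possible, 1, the real one, gave as many as 1921, and the highest other gave 2. A mixed split places treatment differences within its groups, which raises the variance there and lowers the count. Chance was argued against for the MYC target median too, with 1 split as large, although the highest other size was 0.173 against 0.20. A count of 1 in 100, the real split included, is the smallest that this test can give. Chance was not excluded for the number of lists past the threshold. There 5 of the 100 splits, the real one included, gave 17 or more, and the highest other gave 19. Every other split of 5 against 5 arrays keeps part of the treatment difference, however.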

How the results depend on the processing

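Leaving out doxycycline arrays 4 and 5 together was chosen after seeing the data. Genes higher numbered 578 under Welch's test against 880, and genes lower 706 against 1041. Lists past the threshold numbered 2 with an estimated correlation against 17. The MYC target list kept its median of -0.2 with an adjusted p of 0.157 with an estimated correlation; in its other alternatives the median was -0.229 to -0.172 and the list passed. The cause of the lower Welch count and of the lost list calls was not tested. With each array left out in turn, 1374 to 1920 genes changed, 595 to 908 higher and 768 to 1012 lower, 16 to 18 lists passed, and the MYC target median was -0.227 to -0.172. The other settings gave 1284 (Welch's test) to 2515 (trended and robust moderation) changed genes, 1150 and 1870 of them shared with the 1921. With the stroma score as a covariate 1514 genes changed, 1325 of them shared, and without doxycycline arrays 4 and 5 1774 changed, 1346 of them shared. Median centring and a second quantile normalization moved the median change of all genes to 0.0235 and 0.0141. Of 130 named genes 112 passed, 0 of these reversed under any setting, and 98 passed with each array left out in turn. Most had been picked for large changes or small p in these same arrays, so a reversal was unlikely from the start. These counts do not measure the stability of the 1921 calls. Whether the replicate numbers pair the arrays is not known. Deviations of same-numbered arrays correlated by 0.0378, 0.0786, 0.00676, -0.0635 and 0.191, and 2 of 5 vehicle arrays correlated best with their own number. These low values do not exclude pairing or a batch shared by several numbers. With the replicate number as a block 1641 genes changed, 755 higher and 886 lower, 1494 of them shared, 17 lists passed, and the MYC target median was -0.2 (adjusted p = 3.38e-05). The block ended the calls of 9 named genes, MGA (adjusted p = 0.0583), RPL10A, EPRS1, NDUFA9, XIAP, MPO, C1S, SBSN and IER2 (0.0513 to 0.0901 for these), and of no list. Signal over background was not assessed, as the values carry no detection call. The vehicle means of PAGE1, NPFFR2, CAPN3, ERAP2, CIITA, MPO and C1S, which rose, were 3.13, 2.43, 2.30, 3.05, 3.27, 2.93 and 2.46. All lay below the 25th percentile of every array, 3.40 to 3.58.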

Other observations

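The 6 further gene lists below were chosen after the main result was seen, and the genes named with them after their values were seen; the tests of LXR targets and of chromosomes had their criteria written before their values were computed. Fatty acid synthesis genes fell, 4 of 9 with a median of -0.76 (camera, adjusted p = 1.88e-06 over the 6 lists; adjusted p = 0.0217 with an estimated correlation). FASN, the fatty acid synthase, fell by 1.75, the desaturase SCD fell by 1.38, ACLY fell by 0.79 and ACACA fell by 0.76. Replication-dependent histone genes fell, 5 of 15 (adjusted p = 6.20e-05; adjusted p = 0.233 with an estimated correlation), among them H1-3, which fell by 1.02, and H2AC11, which fell by 0.98. Because the fatty acid and histone lists were chosen with the main result known, their p-values give no independent support.

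Of 14 immune checkpoint and complement regulator genes 3 rose and 1 fell, and the list did not pass with camera (adjusted p = 0.136) but did in the exact permutation test of its mean (adjusted p = 0.0476). The complement inhibitors CD55 and CD59 rose by 1.54 and 0.92, PVR fell by 1.74, and CD274 differed by 0.49 (adjusted p = 0.685), beside the rise of PDCD1LG2. Of 15 cancer-testis antigens 2 rose, PAGE1 and MAGEA10, the latter by 0.57 (camera, adjusted p of the list 0.163; exact permutation test, adjusted p = 0.0238). PAGE1, PDCD1LG2 and CD55 had been seen before their lists were written. The exact permutation p-values of both lists thus include genes already known to rise and give no independent support. Of 14 circadian clock genes CRY1 rose by 1.32 and BMAL1 by 0.96, while CIART fell by 0.89 and CLOCK fell by 0.62 (adjusted p of the list 0.795). Of 9 LXR targets, ABCA1 included, 4 rose and 1 fell (adjusted p of the list 0.174).

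The rise of ABCA1 with the fall of cholesterol synthesis raised the hypothesis of shared sterol sensing, with LXR targets other than ABCA1 rising too. These 8 genes did not rise as a list (camera p = 0.647, median 0.204; exact permutation test of their mean, p = 0.976). ABCG1, LPCAT3 and SREBF1 rose by 0.74, 0.60 and 0.62, and APOC1 fell by 1.85, so the test leaves the hypothesis open.

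A change in chromosome copy number or of subclone was tested by chromosome. The largest median change in size was 0.0407, on chromosome 11, under the 0.1 set as the criterion, although that chromosome held 65 higher and 37 lower genes (Fisher's exact test, adjusted p = 0.00494), and the reason was not tested.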
